A study of Mus musculus with 20 samples.

How the data were processed

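RNA from snap-frozen mouse liver tissue was extracted with Trizol, labelled with biotin by a 3'IVT Express protocol and hybridised to Affymetrix arrays, per the labels' protocols. Each array carries many short probes per transcript, grouped into probe sets. Values were used for 20 samples in 4 groups of 5, with the group and the number of each sample taken from the labels. The series' design text mentions a tumour initiation dose of DEN, while the protocols of the samples mention tamoxifen and no DEN, and which holds was not settled. The untreated non-tumour group is named H2O in its labels, while the protocols state standard chow.

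The authors deposited log2 expression values, 1 per probe set and array, and RMA is the tool that the submitters' processing notes name, without a version. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set on a log2 scale, so a shift of all genes in a sample would be removed and folds of very dim genes shrink. The deposited table held 45037 probe sets on 20 arrays with no missing value, ranging from 2.67 to 15.1. The median of an array lay between 5.52 and 5.63 in every group and the upper quartile at 7.52 on average in untreated and phenobarbital-treated non-tumour liver, 7.77 in carcinomas and 7.61 in adenomas, so the arrays were not made identical. No control probe sets were in the table used here, so a planned comparison of 3' and 5' control probe sets as a measure of RNA quality was not run. Arrays have no read depth, and their number limits the precision.

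Probe sets were paired with genes through the platform annotation, with symbols checked by Entrez number against the RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probe sets, 34945 had a single symbol, 34741 of which matched that table, 932 had several and 9160 had none. Genes were named only from probe sets with a single symbol, and each gene was represented by the probe set with the highest mean over the 20 arrays after probe sets ending in _x_at, which can bind related transcripts, were dropped where another existed. This gave 18193 genes, 9010 of them with several probe sets. Among 125 genes chosen by the rule below, 62 had several probe sets, and another probe set of the same gene passed the test in the opposite direction for Top2a, Cpe and Afp. Among called genes this held for 4 pairs of gene and comparison, and not every pair is noted beside its value below. Probe sets without a single symbol were tested separately and are not named.

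Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, both directions) in 1 fit over all 4 groups, with 15 residual degrees of freedom, 3.22 prior degrees of freedom and Benjamini-Hochberg adjustment within a comparison. Every adjusted p of a gene comes from this test with a threshold of 0.05, SE is the standard error of the log2 fold in that fit, and counts of genes changed at least 2-fold use an absolute log2 fold of 1. The comparisons were phenobarbital-treated against untreated non-tumour liver, carcinomas against untreated non-tumour liver, adenomas against phenobarbital-treated non-tumour liver, adenomas against carcinomas, and the difference of the tumour effects as an interaction. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

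Gene lists for drug metabolism, Wnt signalling, liver zonation, hepatocyte functions, metabolism, proliferation, tumour markers, stress, inflammation and other cell types were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives except those said to be chosen later. Of 34 lists, 33 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, adjusted over the lists within a comparison. The imprinted Dlk1-Dio3 list, with 4 measured genes, was not tested. Alternatives were camera with an estimated correlation and fry. Camera compares a list with the other genes, while fry tests whether the genes of a list move, on balance, in 1 direction. Some genes stand in more than 1 list, so lists are not independent. Named genes were the 10 largest rises and 10 largest falls among called genes whose 2 groups did not overlap, passing over gene models without a proper symbol; up to 2 rising and 2 falling called members of each list described; and a fixed panel for Wnt signalling, zonation, drug response and proliferation. The difference of tumour effects used no overlap rule. Gls2, a panel gene, had no probe set with a single symbol in the map used and was not analysed here.

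The alternatives were a filter on dim probe sets (12584 genes kept), the mean of all probe sets of a gene, eBayes with trend and robust settings, centring each array on its median, quantile normalization, array quality weights, the replicate number as a block, a fit of only the groups compared, and each array left out in turn. Leaving out untreated arrays 3 and 4 together was added after seeing the data. No arrays held identical values: within a group the root mean square difference between arrays over genes ranged from 0.236 to 0.717.

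The gene test was tested on simulated data for the 18193 genes, drawn with the SD of each group, with 100 genes shifted by 1 and 100 by 2. For the phenobarbital comparison it recovered 83 and 96 of them, with 11 unshifted genes called, for carcinomas 87 and 98 with 74, for adenomas 87 and 97 with 43, and for the comparison between tumours 88 and 98 with 180. A fit of only the 2 groups called 20, 23, 22 and 16 unshifted genes. The pooled spread therefore calls too many genes in the 3 comparisons that include tumours, whose arrays vary more than those of non-tumour liver, and most between tumours. In a simulated comparison with 1 of the 33 lists shifted, camera called that list and 0 others. The simulated genes were drawn independently of each other, so this says nothing about lists whose genes vary together.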

Results

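Gene expression was measured in liver tissue of male C57BL/6 mice carrying a conditional knockout allele of Apc, the gene of a scaffold protein that marks beta-catenin for destruction and so restrains Wnt signalling. Per the sample protocols, the mice received a single dose of 0.75 mg tamoxifen, a drug used to trigger such alleles, at the age of 6 weeks. The series' design text names a dose of the carcinogen DEN instead, and which holds was not settled. From 1 week later they ate either standard chow or chow with 0.05% phenobarbital for 9 months. Phenobarbital is a sedative that activates the nuclear receptor CAR in hepatocytes and promotes liver tumours in rodents. The 20 samples formed 4 groups of 5: non-tumour liver without phenobarbital (untreated), non-tumour liver with phenobarbital, carcinomas from untreated mice and adenomas from mice on phenobarbital. Every animal carried the knockout allele and no wild-type liver was analysed here. Diet and tumour stage differed together between the tumour groups and cannot be told apart. The labels do not say whether the samples of a group came from separate mice, nor whether tumours and non-tumour samples shared mice, so the p-values measure the spread between these samples. The number of arrays limits the precision of every value, and all levels are log2 expression values.

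Tumour samples separated from non-tumour liver along the leading axes of variation. The first principal component held 74.5% of the variance over 18193 genes and set the carcinomas apart, and the second held 9.51% and set the adenomas apart. Arrays of non-tumour liver correlated with each other across genes at 0.985 to 0.995, adenomas with phenobarbital-treated non-tumour liver at 0.953 to 0.962, and carcinomas with untreated non-tumour liver at 0.732 to 0.822. The median SD of a gene within a group was 0.139 in phenobarbital-treated and 0.166 in untreated non-tumour liver, against 0.211 in carcinomas and 0.23 in adenomas.

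**Figure D1:**
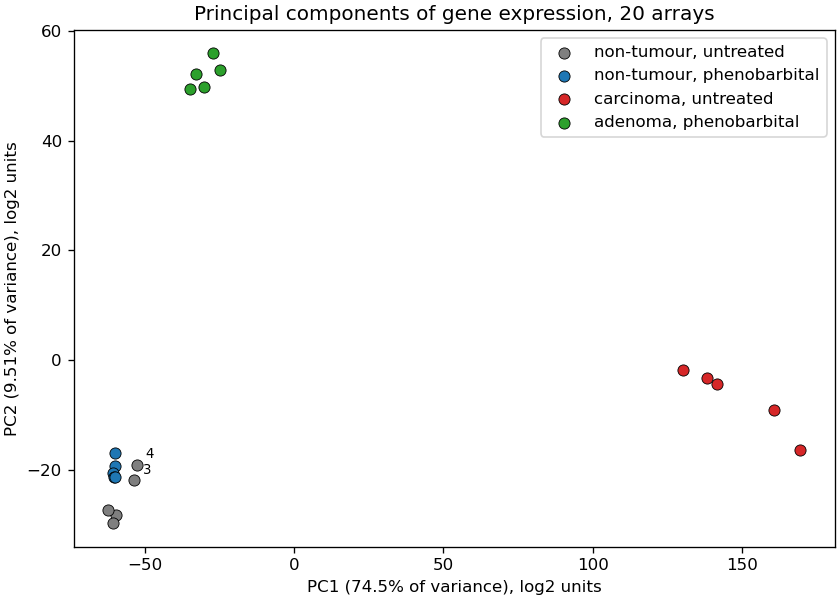
Each point is 1 array, placed by its scores on the first (horizontal) and second (vertical) principal component of log2 expression over 18193 genes, coloured by group, with untreated non-tumour arrays 3 and 4 numbered. The 5 carcinomas lie far to the right on the axis that holds 74.5% of the variance, and the 5 adenomas lie at the top of the axis that holds 9.51%.

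The targeted gene was examined in every group first. Apc read 8.84 ± 0.13 (SD, n = 5) in untreated non-tumour liver, 8.54 ± 0.12 with phenobarbital, 10.68 ± 0.17 in carcinomas and 9.06 ± 0.19 in adenomas. It was therefore higher in carcinomas than in untreated liver by 1.85 (SE 0.10, adjusted p = 6.8e-12) and higher in adenomas than in phenobarbital-treated liver by 0.52 (SE 0.10, adjusted p = 0.0011). The adenoma difference came from the brightest of 4 Apc probe sets: the other 3 gave 0, -0.02 and 0.09, and the mean of the 4 gave 0.15 (adjusted p = 0.22). In carcinomas the 4 probe sets gave 1.85, 2.15, 0.80 and 0.34, the last with adjusted p = 0.08. The part of Apc that is deleted is not given in the sources used here, so these probe sets check nothing about the knockout itself.

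**Figure D2:**
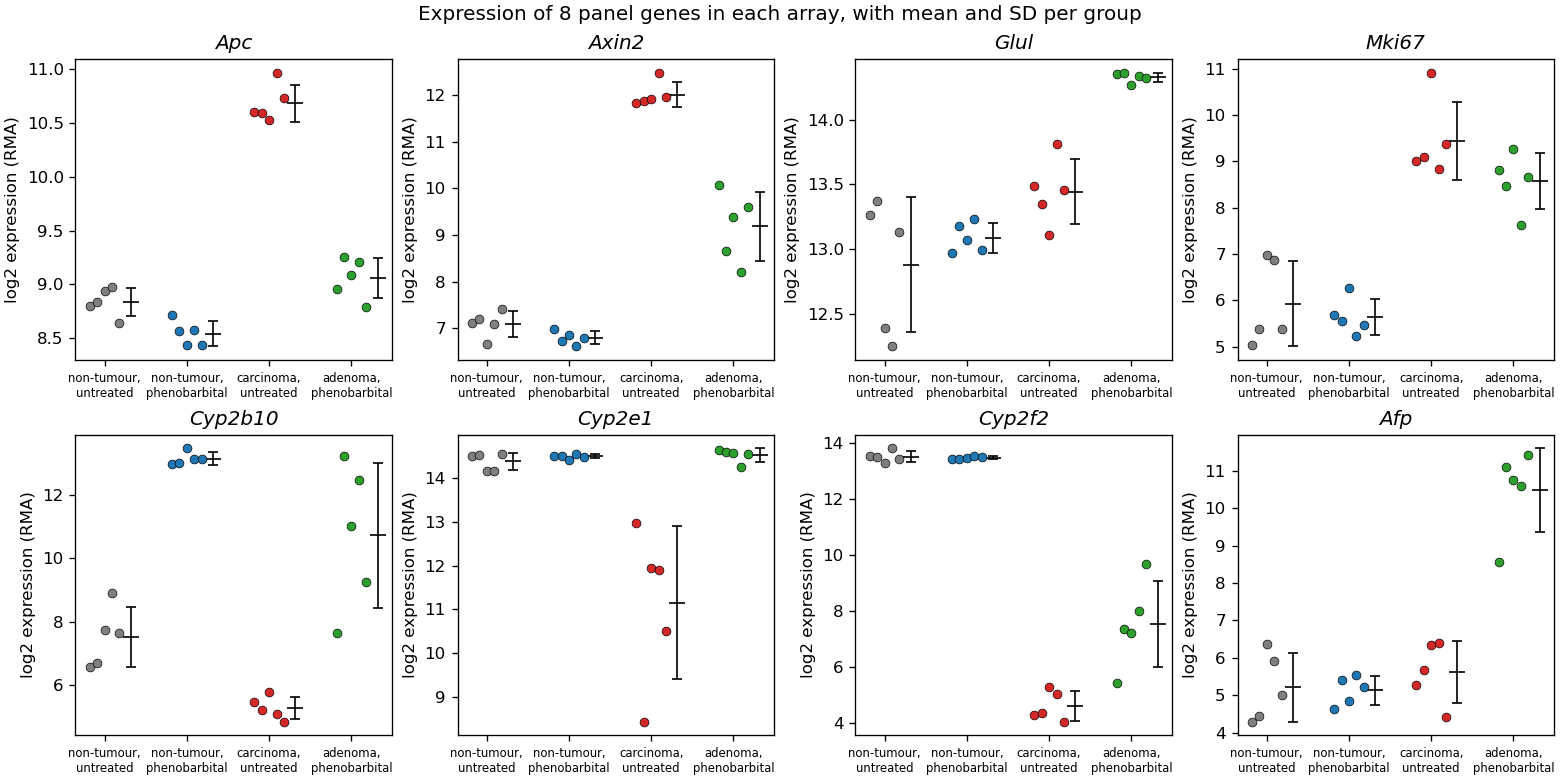
Log2 expression (vertical axes) of 8 genes in each of the 20 arrays (points) by group (horizontal axes), with the mean and SD of the 5 arrays of a group beside them in black. Axin2 read 7.09 and 6.79 in untreated and phenobarbital-treated non-tumour liver, 9.18 in adenomas and 12.02 in carcinomas, whereas Glul peaked in adenomas at 14.33 and Cyp2e1 stayed at 14.52 there while it averaged 11.16 in carcinomas.

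Phenobarbital in non-tumour liver. The comparison asked what 9 months of the drug did to liver outside tumours. Drug-metabolising genes rose most. Sult3a1, a sulfotransferase, went from 3.82 ± 0.45 to 11.01 ± 0.73 (SD, n = 5 each), a rise of 7.19 (SE 0.38, adjusted p = 1e-09). The P450 genes Cyp2c65 (6.12, SE 0.68), Cyp2b13 (5.70, SE 0.52), Cyp2b10 (5.62, SE 0.73), the classical CAR target, Cyp2b9 (5.05, SE 0.78) and Cyp2c55 (3.57, SE 0.46) rose with adjusted p between 3.6e-06 and 0.0031. The carbonyl reductase Cbr3 (3.68), the efflux transporter Abcc4 (3.39), the chemokine scavenger receptor Ackr3 (3.14) and the hydroxyacid oxidase Hao2 (3.14) completed the 10 largest rises. In each of these genes the 5 treated arrays lay above all 5 untreated arrays, which was a condition for being named here.

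In all, 39 of 18193 genes passed the test, 35 higher and 4 lower, and 32 of them changed at least 2-fold, while 1074 had an unadjusted p under the threshold of 0.05. The 4 genes that fell were Serpina4-ps1 (-2.80), Socs2 (-1.91), the growth hormone feedback gene, Mpp4 (-1.20) and Usp6nl (-0.68). Of 18 P450 genes targeted by CAR and PXR, 5 rose and 13 did not pass (9 rose adjusted over the list alone), and of 26 phase II and transport genes 4 rose (9 adjusted over the list alone). Orm3, an acute phase gene, rose by 2.07, but it was the only 1 of 25 acute phase genes to pass over all genes and over the list alone. Of 17 female-biased liver genes 4 rose (4 adjusted over the list alone), among them Sult3a1, Cyp2b13 and Hao2, and camera called all 3 lists (adjusted p = 3.53e-23, 7.3e-16 and 1.18e-09). These calls held with an estimated correlation, at adjusted p = 0.0109, 0.0211 and 0.0211. The female-biased list had a median of 0.39 against a mean of 1.41, with 13 of its 17 genes not past the test. Cyp2b13 also stands in the P450 list, so these calls are not separate results.

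Another 8 lists passed camera with its preset correlation and lost the call with an estimated correlation. The 14 male-biased genes had a median of -0.77, with none past the test over all genes and 5 lower adjusted over the list alone (camera adjusted p = 7.48e-08, adjusted p = 0.143 with an estimated correlation). Interferon response genes had a median of 0.39, with 0 of 25 past the test over all genes and 4 higher adjusted over the list alone (camera adjusted p = 5.5e-09, adjusted p = 0.355 with an estimated correlation). Macrophage and Kupffer cell genes had a median of 0.40, with 0 of 25 past the test either way (camera adjusted p = 6.16e-05, adjusted p = 0.621 with an estimated correlation). The medians were 0.25 for NRF2 targets, where Cbr3 alone passed over all genes and 2 genes adjusted over the list alone, 0.17 for lipogenesis, 0.21 for adipose tissue, -0.19 for periportal and -0.14 for urea cycle genes, the last 4 lists with no member past the test either way. For these 5 lists camera gave adjusted p = 1.92e-05, 0.00144, 0.00593, 0.0188 and 0.0251, and with an estimated correlation adjusted p = 0.481, 0.25, 0.104, 0.621 and 0.732. Of 25 pericentral genes 2 rose, the same adjusted over the list alone, without a call for the list (camera adjusted p = 0.166; 0.045 without untreated array 1, median 0.10). Rhbg, an ammonium transporter gene, rose by 1.28 (SE 0.22, adjusted p = 0.012). It read 0.95 with adjusted p = 0.092 without untreated arrays 3 and 4. The glutathione transferase gene Gstm3 rose by 2.33 (SE 0.46, adjusted p = 0.034). The Gstm3 call ended without any 1 of 8 arrays (untreated 1, 2 and 5 and phenobarbital 1 to 5, adjusted p = 0.072 to 0.12, values 2.07 to 2.38). Axin2 differed by -0.30, Glul by 0.21, Lgr5 by -0.30 and Cyp2e1 by 0.11, each with adjusted p = 1.0, and Cyp1a2 by 1.25 (SE 0.55, adjusted p = 0.79). The treated arrays of Cyp1a2 (13.15 to 13.41) all lay above the untreated ones (10.72 to 12.92). Its SE also takes in the carcinomas, which ran from 4.97 to 8.57. Meg3, an imprinted noncoding RNA, differed by 2.0 with an SE of 1.19 (adjusted p = 0.94). It read 6.29 to 8.95 in untreated and 8.56 to 9.98 in phenobarbital-treated arrays. The SE of a gene rests on the spread of all 4 groups, and Meg3 ran from 5.62 to 13.25 in adenomas, which are not compared here.

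The number of genes past the test depended on which spread was used: it was 265 (186 higher, 79 lower) when only the 10 non-tumour arrays entered the fit and 205 with array weights, and all 39 genes were among them in both. Single arrays also moved it, to 23 without phenobarbital array 3 and to 25 without phenobarbital array 2, and it was 28 without untreated arrays 3 and 4, an alternative chosen after seeing the data. Without those 2 arrays Cyp2b9 (4.58, adjusted p = 0.064) and Hao2 (3.15, adjusted p = 0.12) no longer passed. Socs2 lost its call without any 1 of the 10 arrays (adjusted p = 0.064 to 0.17), Usp6nl without 7 of them (untreated 1, 3 and 4 and phenobarbital 2 to 5, at most 0.13), Hao2 without 6 (untreated 1, 2 and 4 and phenobarbital 1 to 3, at most 0.079), Serpina4-ps1 without phenobarbital 1, 2 or 3 (at most 0.059) and Cbr3 without phenobarbital 3 (0.053). The periportal call was lost without untreated array 4 (adjusted p = 0.16), and the urea cycle call without untreated array 4 (0.17) or phenobarbital array 1 (0.061). Without untreated arrays 3 and 4 both were lost (0.26 and 0.21), and with centring both lay at the threshold (0.05). Socs2 read -0.76 (adjusted p = 0.12) and Usp6nl -0.47 (0.52) with the mean of all probe sets, and without untreated arrays 3 and 4 they had adjusted p = 0.24 and 0.26. Socs2 also lost its call with trend and robust settings (0.061) and Usp6nl with the replicate block (0.054). Some lists without a call gained one: cell cycle genes downward without untreated array 1 (median -0.24, adjusted p = 0.0053), untreated array 2 (-0.17, 0.0043) or phenobarbital array 3 (-0.15, 0.013), secretory and identity genes downward with only the 2 groups fitted (-0.05, 0.00012), and fetal liver and tumour markers upward without untreated arrays 3 and 4 (0.31, 2e-04). B and plasma cell genes gained one upward with array weights (0.16, 0.045), with only the 2 groups fitted (0.14, 0.026), and without phenobarbital array 2 (0.14, 0.042), 3 (0.20, 0.037) or 5 (0.18, 0.031).

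**Figure D3:**
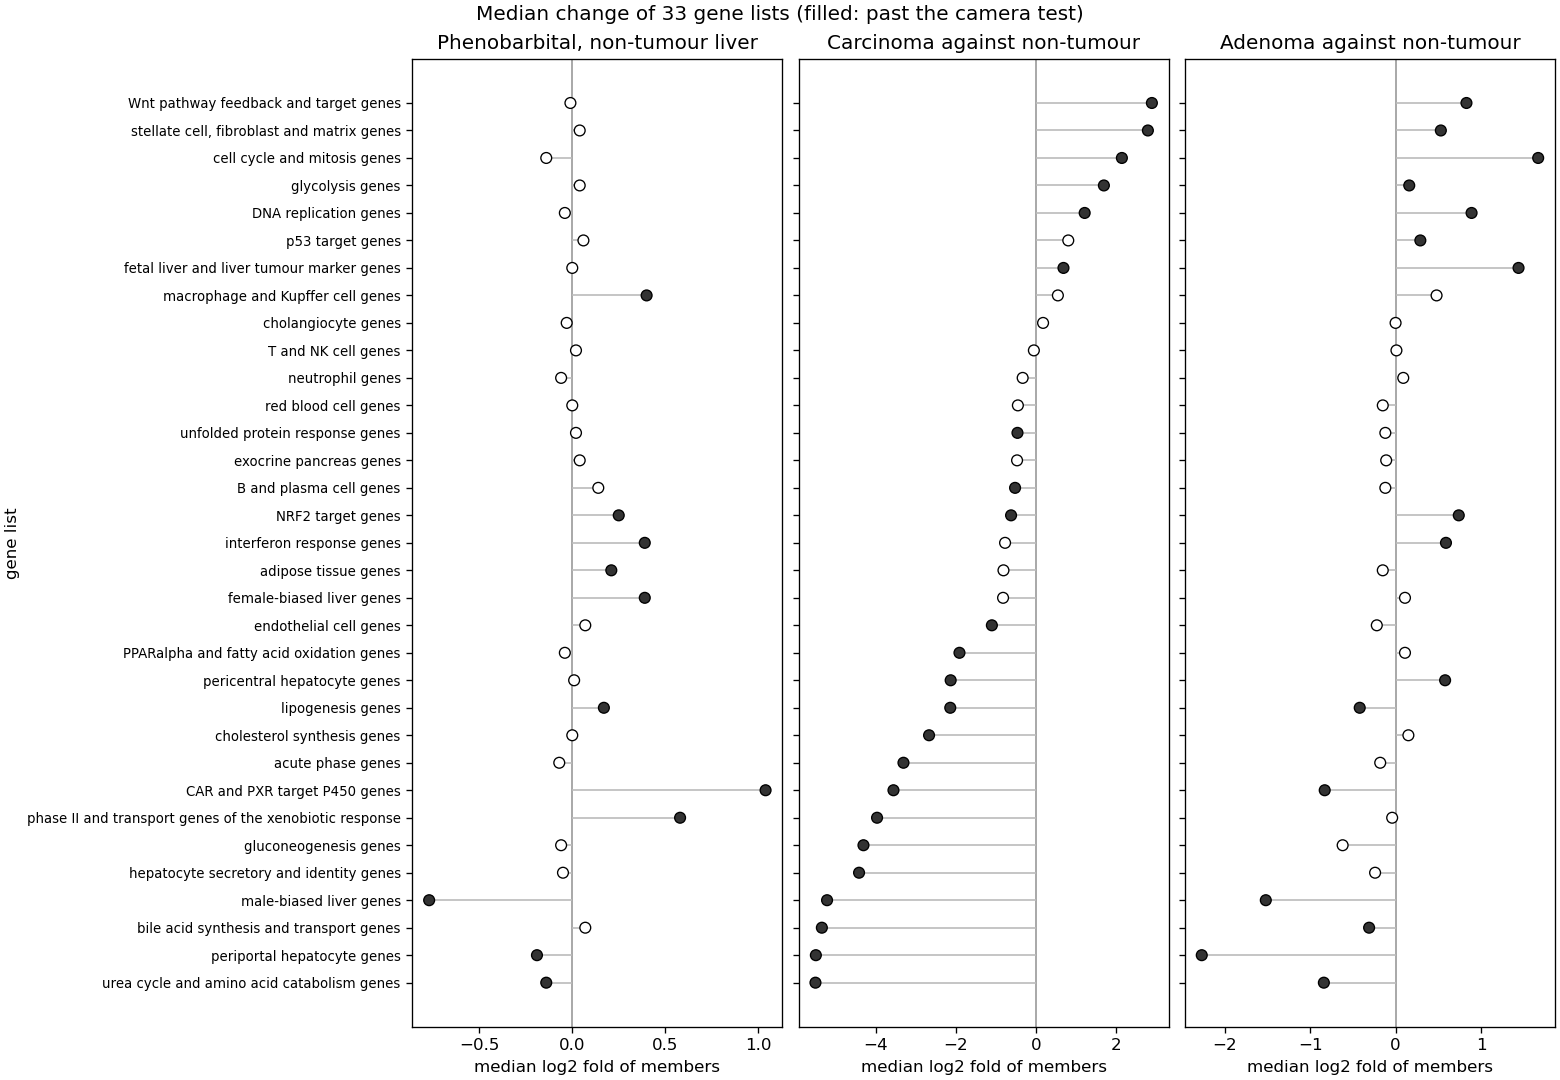
Median log2 fold of the members of 33 gene lists (horizontal axes) in the phenobarbital, carcinoma and adenoma comparisons, each list in the same line across panels, with filled points for lists past camera with its preset correlation and open points for the others. Scales differ between panels: the hepatocyte list has its median at -4.42 in carcinomas and at -0.24 in adenomas, and the Wnt list at 2.90 and 0.83.

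Carcinomas against untreated non-tumour liver. This comparison described tumours that arose without the drug. Their largest rises were in genes that were close to the floor of the arrays in liver. Wif1, a secreted Wnt inhibitor, went from 3.36 ± 0.20 to 13.73 ± 0.03 (SD, n = 5 each), a rise of 10.37 (SE 0.59, adjusted p = 7.3e-12), and Bex1, a brain-expressed X-linked gene, rose by 10.29 (SE 0.50). Nptx1 (9.19), the cardiac troponin gene Tnnt2 (9.04), Armh4 (9.03), the growth factor Ptn (9.01), the prohormone-processing enzyme Cpe (8.82), Dner (8.68), Egfl6 (8.60) and the phospholipase Pla2g5 (8.58) followed. The largest falls were in hepatocyte enzymes and secreted products: Cyp2f2, a periportal P450, fell from 13.50 ± 0.20 to 4.59 ± 0.53, a change of -8.91 (SE 0.47, adjusted p = 2.6e-12), ahead of Hamp, which encodes the iron hormone hepcidin (-8.17), Upp2 (-7.59), Ugt2b1 (-7.55), the histidine ammonia-lyase Hal (-7.39), Etnppl (-7.33), Keg1 (-7.33), the urea cycle enzyme Otc (-7.31), Cyp4a12a (-7.22) and Bhmt2 (-7.19).

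Most Wnt pathway genes rose. Of 29 feedback and target genes 22 rose and 3 fell, the same numbers adjusted over the list alone, with a median of 2.90 (camera adjusted p = 3.44e-07, adjusted p = 0.0874 with an estimated correlation). Besides Wif1, the Wnt inhibitor gene Apcdd1 rose by 7.69, the feedback gene Axin2 by 4.93 (SE 0.25, adjusted p = 1.3e-12) and Ccnd1, which encodes cyclin D1, by 3.78, and Ctnnb1, which encodes beta-catenin, rose by 1.89 (SE 0.11, adjusted p = 2e-11), while Lgr4 (-1.77) and Fzd7 (-1.40) fell. Lgr5 rose by 1.48 and Glul, the pericentral glutamine synthetase gene, by 0.56 (SE 0.18, adjusted p = 0.0094). Without untreated arrays 3 and 4 these 2 genes read 1.04 (adjusted p = 0.056) and 0.19 (adjusted p = 0.19). Glul also lost its call when only the arrays of these 2 groups were fitted (adjusted p = 0.052).

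Most genes of the periportal and pericentral lists and of the lists of hepatocyte functions fell. Of 27 secretory and identity genes 26 fell, F9, the gene of a clotting factor, by a change of -6.28, and Foxa2 rose by 1.79 (camera adjusted p = 1.77e-07, adjusted p = 0.327 with an estimated correlation). Carcinoma array 2 was lowest on this list, with a median of -4.11 against the middle of its group, where the other 4 lay between -1.46 and 0.92. The list kept its call without this array. Of 24 periportal genes 21 fell, with a median of -5.50 (camera adjusted p = 4.84e-08, adjusted p = 0.0947 with an estimated correlation). Of 25 pericentral genes 18 fell and 6 rose: Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -6.30, Cyp1a2 by -5.14, Cyp2e1 by -3.22 and Oat by -1.45, against rises of Axin2 and of the amino acid transporter gene Slc1a4 (1.58; camera adjusted p = 0.00398, adjusted p = 0.293 with an estimated correlation). All 21 urea cycle and amino acid genes fell, with a median of -5.51 (camera adjusted p = 7.51e-11, adjusted p = 0.0874 with an estimated correlation), as did all 21 bile acid genes, among them the bile acid importer gene Slc10a1 (-6.87) and Baat (-6.73; camera adjusted p = 4.33e-10, adjusted p = 0.0947 with an estimated correlation). All 14 male-biased genes fell, Elovl3 by -7.16 (camera adjusted p = 9.98e-07, adjusted p = 0.11 with an estimated correlation). In each of these 6 lists the counts were the same adjusted over the list alone.

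Most drug metabolism and lipid genes were lower as well. Falls passed in 13 of 18 CAR and PXR target P450 genes (camera adjusted p = 6.69e-05, adjusted p = 0.206 with an estimated correlation), Cyp2c37 by -6.56, and Nr1i3, the gene of CAR, changed by -3.82 (SE 0.34). Of 26 phase II and transport genes 22 fell, the carboxylesterase Ces2a by -6.74, while Abcc4 (4.66) and Abcb1a (2.14) rose (camera adjusted p = 2.5e-07, adjusted p = 0.0958 with an estimated correlation). Falls passed in 22 of 25 lipogenesis genes, Thrsp by -6.22, against a rise of Scd2 by 3.47, in 18 of 19 cholesterol synthesis genes, Sc5d by -4.16, in 22 of 23 fatty acid oxidation genes and in 8 of 9 gluconeogenesis genes. Camera gave adjusted p = 4.82e-07, 4e-08, 1.88e-08 and 0.000543 for these 4 lists, and with an estimated correlation adjusted p = 0.0874, 0.206, 0.0958 and 0.0958. Acute phase genes fell in 21 of 25 (camera adjusted p = 0.000113, adjusted p = 0.338 with an estimated correlation), and NRF2 targets fell in 10 of 17 and rose in 1 (camera adjusted p = 0.0317, adjusted p = 0.511 with an estimated correlation). The NRF2 call ended without untreated arrays 3 and 4 (adjusted p = 0.057). Glycolysis genes rose in 12 of 16: Pkm, the pyruvate kinase gene of proliferating and muscle cells, by 5.88 and Pfkp by 4.31, while the liver pyruvate kinase gene Pklr changed by -4.62 (camera adjusted p = 7.1e-05, adjusted p = 0.0958 with an estimated correlation). In each of these 9 lists the counts were the same adjusted over the list alone.

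Most proliferation genes were higher, while tumour markers moved both ways. Of 27 cell cycle and mitosis genes 24 rose, Top2a by 3.72 and Mki67 by 3.52 (SE 0.42, adjusted p = 3.8e-07), and of 27 DNA replication genes 21 rose and 5 fell (camera adjusted p = 1.73e-06 and 0.00239, adjusted p = 0.338 and 0.444 with an estimated correlation). Another Top2a probe set changed by -0.43. Of 27 fetal liver and liver tumour markers 12 rose and 4 fell, among them Bex1 and S100a6 (8.17) against Krt8 (-2.93), and Afp, the fetal albumin-like gene, differed by 0.41 with an SE of 0.50 (adjusted p = 0.47), while another of its 5 probe sets fell by a change of -0.28 (for the list, camera adjusted p = 0.0211, adjusted p = 0.338 with an estimated correlation and 0.086 with the filter on dim probe sets). Among 18 p53 targets 10 rose, Cdkn1a by 4.48, and 5 fell, without a call for the list (camera adjusted p = 0.105). The counts of these 4 lists were the same adjusted over the list alone.

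Markers of other cell types moved in different directions. Of 30 stellate cell, fibroblast and matrix genes 23 rose and 2 fell, with a median of 2.80, Acta2, the smooth muscle actin gene, by 7.20 and Vim by 5.29 (camera adjusted p = 1.1e-06, adjusted p = 0.244 with an estimated correlation). Of 26 endothelial genes 17 fell and 3 rose (19 and 3 adjusted over the list alone): the sinusoidal genes Clec4g (-5.22) and Stab2 (-3.80) fell while Flt1 (3.51) and Cd34 (3.19) rose (camera adjusted p = 0.000543, adjusted p = 0.0958 with an estimated correlation). Macrophage genes split, with 11 of 25 higher and 9 lower and a median of 0.55 against a mean of -0.09: Lgals3 rose by 3.22, and the Kupffer cell genes Cd5l (-4.02) and Clec4f (-3.63) fell (camera adjusted p = 0.918). Cholangiocyte genes rose in 5 of 16, Krt23 by 6.41 and Cd24a by 5.73, and fell in 3 (camera adjusted p = 0.392). Of 15 B and plasma cell genes 11 fell (camera adjusted p = 0.0371, adjusted p = 0.327 with an estimated correlation), a call that ended without carcinoma array 2 (adjusted p = 0.061), with the filter on dim probe sets (0.12), with quantile normalization (0.052) and, at the threshold, with the mean of all probe sets (0.05). Of 20 unfolded protein response genes 12 fell (camera adjusted p = 0.0499, adjusted p = 0.427 with an estimated correlation), a call that ended without any 1 of 6 arrays (untreated 1, 2 and 4 and carcinoma 1, 2 and 5, adjusted p = 0.054 to 0.085). It also ended without untreated arrays 3 and 4 (0.08), with trend and robust settings (0.051), with centring (0.054) and with quantile normalization (0.073). The remaining lists gave no call. T and NK cell genes rose in 5 of 21 and fell in 5 (4 and 3 adjusted over the list alone), with a median of -0.05 against a mean of 0.22 (camera adjusted p = 0.942). Neutrophil genes fell in 6 of 14 (5 adjusted over the list alone), red blood cell genes in 4 of 6, adipose tissue genes in 9 of 10, interferon response genes in 14 of 25 and female-biased genes in 7 of 17, with camera adjusted p = 0.185, 0.303, 0.0808, 0.114 and 0.0745. The female-biased list passed downward with the filter on dim probe sets (median -0.95, adjusted p = 0.043) and with only the 2 groups fitted (-0.82, adjusted p = 0.0064). Exocrine pancreas genes fell in 8 of 12, while the lipase-related gene Pnliprp1 rose by 6.93, so that the median was -0.47 and the mean 0.14 (camera adjusted p = 0.115).

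The limma test called 12544 of 18193 genes, 5709 higher and 6835 lower, and 5128 of them differed at least 2-fold, 3048 higher and 2080 lower. The balance turned with the filter on dim probe sets (5198 higher, 4396 lower) and held with quantile normalization (5146 and 6566). The median log2 fold over all genes was -0.118, and 0.084 with the filter on dim probe sets. Of the 23 lists called with the preset correlation none held with an estimated correlation, for which the lowest adjusted p was 0.0874. None of the 20 leading genes lost its call under any setting tried.

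Adenomas against phenobarbital-treated non-tumour liver. This comparison described tumours that arose on the drug, against liver on the same diet. Nupr1, a stress-response transcription regulator, rose most, from 5.23 ± 0.21 to 10.72 ± 1.14 (SD, n = 5 each; 5.49, SE 0.35, adjusted p = 2.4e-09), and Afp followed, from 5.13 ± 0.38 to 10.48 ± 1.12 (5.36, SE 0.50, adjusted p = 2.5e-07). The sulfotransferase Sult2a2 (4.93), the plasminogen activator Plat (4.86), Igfbp1 (4.74), the collagen Col8a1 (4.67), Cpe (4.52), Scd2 (4.50), Calml4 (4.49) and the serine synthesis enzyme Psat1 (4.48) completed the 10 largest rises. Sult3a1 (-6.52, SE 0.38), Hal (-6.47), the urinary protein gene Mup10 (-6.01), Cyp2f2 (-5.93), the urea cycle enzyme Arg1 (-5.81), Elovl3 (-5.74), Mup3 (-5.21), Hamp (-5.18), Wfdc21 (-5.03) and Amdhd1 (-4.83) fell most. A second Cpe probe set changed by -1.21, and Mup and Cyp2c genes have near-identical family members, so probe sets of these genes can read more than 1 of them.

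Most periportal genes fell, while 11 of 25 pericentral and 15 of 29 Wnt genes rose. Of 24 periportal genes 16 fell and none rose, with a median of -2.27 (16 adjusted over the list alone; camera adjusted p = 1.92e-10, adjusted p = 0.106 with an estimated correlation). Of 25 pericentral genes 11 rose and none fell (11 and 1 adjusted over the list alone): the glutamate transporter gene Slc1a2 by 3.20, Slc1a4 by 2.94 and Glul from 13.09 ± 0.12 to 14.33 ± 0.04, by 1.24 (SE 0.18, adjusted p = 4.8e-05; for the list, camera adjusted p = 8.86e-06, adjusted p = 0.167 with an estimated correlation). Cyp2e1 and Cyp1a2 differed by 0.03 and 0.01 (adjusted p = 0.98 and 0.99), and Oat by 0.65 (adjusted p = 0.09). Oat passed with only the 2 groups fitted (adjusted p = 0.00094) and with array weights (0.67, adjusted p = 0.012). Of 29 Wnt genes 15 rose and none fell (15 and 2 adjusted over the list alone), Nkd1 by 3.04, Axin2 by 2.39 (SE 0.25, adjusted p = 1.2e-06), Ccnd1 by 1.98 and Lgr5 by 1.71 (SE 0.41, adjusted p = 0.0046; for the list, camera adjusted p = 7.29e-05, adjusted p = 0.167 with an estimated correlation). Ctnnb1 differed by 0.13 (adjusted p = 0.46).

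Of the 35 genes that phenobarbital had raised in non-tumour liver, 18 were lower and 6 higher in the adenomas. Of 18 CAR and PXR target P450 genes 7 fell and none rose (7 adjusted over the list alone), Cyp2c65 by -4.51, Cyp2b13 by -4.27 and Cyp2c55 by -1.94 (camera adjusted p = 0.00846, adjusted p = 0.529 with an estimated correlation). Cyp2b10 changed by -2.41 (SE 0.73, adjusted p = 0.02) and ranged from 7.64 to 13.22 among the 5 adenomas, and the call ended without adenoma array 5 (-2.05, adjusted p = 0.053) or with only the 2 groups fitted (adjusted p = 0.061). Of 26 phase II and transport genes 5 fell, Ces2a by -2.64 and Gstt3 by -2.57, and 3 rose, Abcb1a by 2.12 and Abcc4 by 1.61 (5 and 4 adjusted over the list alone; camera adjusted p = 0.795). Nr1i3 differed by -0.85 (adjusted p = 0.077), and it passed without adenoma array 2 (-1.16, adjusted p = 0.0095) and with array weights (-1.07, adjusted p = 0.016). Of 17 NRF2 targets 8 rose, Srxn1 by 1.86 (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00037, adjusted p = 0.509 with an estimated correlation). Adenoma array 5 was highest on this list, with a median of 1.38 against the middle of its group, where the other 4 lay between -0.31 and 0.22. The list kept its call without this array.

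Among the metabolic lists, 13 of 21 urea cycle and amino acid genes fell (14 adjusted over the list alone; camera adjusted p = 2.04e-07, adjusted p = 0.167 with an estimated correlation). Of 25 lipogenesis genes 10 fell, Cidea by -4.47, and Scd2 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.000294, adjusted p = 0.167 with an estimated correlation). Of 21 bile acid genes 6 fell, Cyp8b1 by -2.87, and Cyp7a1 rose by 0.91 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0129, adjusted p = 0.585 with an estimated correlation). The Cyp7a1 call ended without any 1 of 4 arrays (phenobarbital 2 and 4 and adenoma 1 and 2, adjusted p = 0.055 to 0.094). Of 14 male-biased genes 7 fell (9 adjusted over the list alone; camera adjusted p = 0.00037, adjusted p = 0.432 with an estimated correlation). Glycolysis genes rose in 6 of 16, Pkm by 1.71 (6 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.458 with an estimated correlation), and this call ended without adenoma array 4 (median 0.09, adjusted p = 0.085) or with the filter on dim probe sets (0.25, adjusted p = 0.069). Secretory and identity genes gave no call, with 2 of 27 lower and 1 higher (2 lower adjusted over the list alone; camera adjusted p = 0.339), nor did the gluconeogenesis, cholesterol and fatty acid oxidation lists (0.109, 0.795 and 0.128), although Fgf21, a hormone of the fasting response, rose by 3.94 and Pdk4 by 2.26. With only the 2 groups fitted the secretory and identity list (median -0.24, adjusted p = 0.0012) and the gluconeogenesis list (-0.62, adjusted p = 0.026) passed downward, and without adenoma array 4 the fatty acid oxidation list passed upward (0.15, adjusted p = 0.034). Acute phase genes, with 2 of 25 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.302), also passed downward with only the 2 groups fitted (-0.18, adjusted p = 0.012).

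Proliferation genes rose in nearly the whole list: 25 of 27 cell cycle and mitosis genes (26 adjusted over the list alone), Ube2c by 2.97 and Mki67 by 2.93 (SE 0.42, adjusted p = 4.3e-05; for the list, camera adjusted p = 1.33e-16, adjusted p = 0.184 with an estimated correlation). Of 27 DNA replication genes 17 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 2.31e-06, adjusted p = 0.458 with an estimated correlation). Fetal liver and tumour markers rose in 16 of 27, Afp and Scd2 foremost, and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 7.22e-09, adjusted p = 0.106 with an estimated correlation). Interferon response genes rose in 9 of 25 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.69 with an estimated correlation and 0.053 with the filter on dim probe sets). Of 18 p53 targets 6 rose, Cdkn1a by 2.38, and 2 fell (6 and 3 adjusted over the list alone), and camera put this list at the threshold itself (adjusted p = 0.05, adjusted p = 0.458 with an estimated correlation), with the call lost without any 1 of 5 arrays (phenobarbital 3 and 4 and adenoma 1, 3 and 4, adjusted p = 0.055 to 0.13). It was also lost with the filter on dim probe sets (0.094), the mean of all probe sets (0.064), centring (0.064), quantile normalization (0.1) and the replicate block (0.052).

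Some markers of other cell types also changed. Of 30 stellate cell, fibroblast and matrix genes 9 rose and 5 fell, the same adjusted over the list alone (median 0.53, camera adjusted p = 0.0357, adjusted p = 0.802 with an estimated correlation), and the call ended without phenobarbital array 2 (adjusted p = 0.054), adenoma array 3 (0.088) or adenoma array 4 (median 0.23, adjusted p = 0.24). It also ended with the filter on dim probe sets (adjusted p = 0.15), with arrays centred on their median (0.064) and with array weights (0.13). Endothelial genes gave no call, with 4 of 26 higher, among them Cd34 by 3.01, and 7 lower, among them Clec4g by -1.61 (camera adjusted p = 0.27). Macrophage genes gave none either, with 5 of 25 higher, among them Lgals3 by 2.45, and 7 lower (11 and 8 adjusted over the list alone; camera adjusted p = 0.79).

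The limma test called 4470 genes, 2433 higher and 2037 lower, and 1167 of them differed at least 2-fold, 718 higher and 449 lower. The balance turned with the mean of all probe sets (2062 higher, 2132 lower) and with quantile normalization (2135 and 2167). It held with the filter on dim probe sets (2440 and 1839). Of the 16 lists called with the preset correlation none held with an estimated correlation, for which the lowest adjusted p was 0.106, and none of the 20 leading genes lost its call under any setting tried.

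Adenomas with phenobarbital against carcinomas without. The direct comparison of the tumour groups showed liver genes higher in adenomas and the genes that led the carcinoma list higher in carcinomas. Cyp2c37 (7.47, SE 0.63), Cyp7a1 (7.0, SE 0.30), the decarboxylase Ddc (6.77), the glutathione transferase Gsta2 (6.73), Ly6d (6.61), the bile acid enzyme Akr1d1 (6.52), Ces1g (6.49), Cyp2c54 (6.46), Fabp2 (6.46) and Akr1c19 (6.45) were highest in adenomas relative to carcinomas. Armh4 (-9.03, SE 0.36), Wif1 (-8.89), Tnnt2 (-8.81), Egfl6 (-8.50), Pla2g5 (-8.27), Dner (-8.17), the ephrin receptor Epha7 (-8.08), Ptn (-7.87), Gpr37 (-7.73) and the T-box gene Tbx4 (-7.67, SE 0.10) were lowest. Tbx4 read 11.40 ± 0.17 in carcinomas and 3.73 ± 0.14 in adenomas (SD, n = 5 each). Apc was lower in adenomas by -1.62, Axin2 by -2.83 and Ctnnb1 by -1.84, Glul was higher by 0.88 (SE 0.18, adjusted p = 0.00027) and Afp by 4.86, and Lgr5 did not differ beyond its error (-0.07, SE 0.41, adjusted p = 0.9). Mki67 differed by -0.88 (adjusted p = 0.076), which passed without adenoma array 3 (-1.05, adjusted p = 0.046) and with the replicate number as a block (-0.88, adjusted p = 0.024), and Meg3 by 1.59 (adjusted p = 0.25), which passed without carcinoma array 3 (2.62, adjusted p = 0.04).

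By list, 26 of 27 secretory and identity genes, 18 of 18 CAR and PXR target P450 genes, 21 of 25 pericentral and 17 of 24 periportal genes were higher in adenomas, the same numbers adjusted over the list alone (camera adjusted p = 2.33e-07, 6.18e-07, 1.1e-06 and 0.00094, adjusted p = 0.299, 0.0983, 0.0974 and 0.224 with an estimated correlation). Of 29 Wnt genes 18 were lower and 3 higher, Apcdd1 differing by -7.36, and of 30 stellate cell, fibroblast and matrix genes 23 were lower and none higher, Acta2 differing by -5.18 (camera adjusted p = 7.94e-06 and 8.02e-07, adjusted p = 0.0974 and 0.224 with an estimated correlation). Of 16 glycolysis genes 13 were lower and 1 was higher, whereas 20 of 26 endothelial genes were higher and 3 lower (camera adjusted p = 0.000123 and 0.000548, adjusted p = 0.0974 for both with an estimated correlation). The counts of these 4 lists were the same adjusted over the list alone. Cell cycle genes gave no call, with 2 of 27 higher and 6 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.209). The limma test called 11308 genes, 6118 higher and 5190 lower in adenomas, 4791 of them at least 2-fold, and 22 lists, none of which held with an estimated correlation (lowest adjusted p = 0.0974). The balance of genes turned with the filter on dim probe sets (4426 higher, 4696 lower), while centring gave 7414 higher and 4818 lower.

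The tumour effects, each against its own control liver, overlapped in part. Of the 18193 genes, 3559 were called in both: 1575 were higher in both tumour types, against 763.5 for independent lists, 1397 were lower in both, against 765.3, and 587 went opposite ways, 261 of them higher in carcinomas and 326 higher in adenomas. The log2 folds correlated across genes at r = 0.44 (Spearman's rho 0.40), where genes are not independent replicates and the comparisons share no arrays. Genes higher in both included Axin2, Ccnd1, Mki67, Nupr1, Plat, Cpe and Scd2, and genes lower in both included Cyp2f2, Hal, Hamp and Elovl3. For Cpe another probe set was lower in adenomas. The difference between the effects was tested as an interaction and passed for 8477 genes.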

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

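Of the tests below, the test for carcinoma tissue in untreated arrays 3 and 4 and the tests on the 18 genes lower in adenomas were chosen only after the result was seen. The difference between the tumour effects, each against its own control liver, was tested as an interaction and passed for 8477 genes. Of 100 splits of the arrays 1, the real split, gave as many, which argues against chance only if the arrays are independent samples. The highest other gave 8439 genes and kept all 5 carcinomas together with another assignment of non-tumour arrays. The count therefore follows the carcinomas standing apart, and the splits say little about which control liver belongs with which tumour. The genes with the largest positive difference, higher in the adenoma effect, were Cyp7a1 (7.21), Ddc (6.85), Fabp2 (6.54), Bhmt2 (6.48), Cyp2c68 (6.41), Apom (6.39), Hgd (6.33), Cyp4f14 (6.26), Aox3 (6.22) and Gsta2 (6.19). The largest negative differences were in Armh4 (-9.23), Wif1 (-9.04), Tnnt2 (-8.82), Epha7 (-8.58), Egfl6 (-8.43), Pla2g5 (-8.34), Dner (-8.29), Gpr37 (-7.91), Ptn (-7.89) and Tbx4 (-7.70). Among the fixed panel, Cyp1a2 (5.16), Afp (4.94), Cyp2e1 (3.25), Cyp2f2 (2.98), Nr1i3 (2.96), Oat (2.10) and Glul (0.67) differed upward, and Axin2 (-2.54), Ccnd1 (-1.80), Ctnnb1 (-1.76) and Apc (-1.33) downward. The Glul difference (adjusted p = 0.035) was lost without any 1 of 7 arrays (untreated 1, 2 and 5, phenobarbital 1 and 5, carcinoma 2 and 3, adjusted p = 0.055 to 0.072, values 0.55 to 0.65).

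The same test gave 19 gene lists with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.0932), against 27 with fry. The median differences were positive for gluconeogenesis (4.11), bile acid (4.03), secretory and identity (4.02), urea cycle (3.56), phase II (3.41), pericentral (3.30), male-biased (3.21), acute phase (3.18), periportal (2.82), CAR and PXR target P450 (2.74), cholesterol (2.7), fatty acid oxidation (2.50), lipogenesis (1.82), NRF2 (1.71), endothelial (1.31) and interferon (1.29) genes. They were negative for stellate cell (-1.97), Wnt (-1.70) and glycolysis (-1.34) genes. Cyp2b10 (-0.18, adjusted p = 0.9), Cyp2c55 (1.5, adjusted p = 0.067) and Mki67 (-0.59, adjusted p = 0.43) did not pass this test. Cyp2c55 passed with arrays centred on their median (1.60, adjusted p = 0.049), with quantile normalization (1.62, adjusted p = 0.047), and without untreated array 2 (1.74, adjusted p = 0.038), adenoma array 1 (1.84, adjusted p = 0.019) or adenoma array 4 (1.78, adjusted p = 0.029).

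Some single arrays lay far from the other 4 of their group, by the gap to the nearest array over the range of the group. Chance flags about 1 in 20 groups, which gives 25 of the 500 sets of 5 arrays checked over 125 genes, and 29 were found. In carcinomas these were Oat (0.95), Mirg (0.925), Armh4 (0.871), Acta2 (0.795), Axin2 (0.792), Ctnnb1 (0.788), Dner (0.779), Keg1 (0.756), Mki67 (0.746), Bex1 (0.739), Psat1 (0.736) and Meg3 (0.725), 8 of them in carcinoma array 3. In adenomas they were Mirg (0.943), Apcdd1 (0.892), Abcc4 (0.777), Plat (0.764), Cyp2e1 (0.744), Dner (0.725), Cd5l (0.721) and Stab2 (0.712). In phenobarbital-treated liver they were Bhmt2 (0.919), Nr1i3 (0.829), Tnnt2 (0.802), Cd34 (0.796), Etnppl (0.795) and Ctnnb1 (0.718), and in untreated liver Oat (0.86), Apom (0.808) and Apcdd1 (0.791).

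Probe sets without a single gene symbol, which no comparison of genes uses, also passed the test: 8 of 10092 for phenobarbital in non-tumour liver, 5671 for carcinomas, 1013 for adenomas, 4541 between the tumour groups and 3006 for the difference of the tumour effects.

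In carcinomas hepatocyte genes were lower while stellate cell genes were higher. A lower share of hepatocytes alone, with all other cell types raised alike, is argued against by the medians of 5 cell type lists, which lay 3.91 apart (95% interval 2.62 to 5.03), from stellate cell genes at 2.80 to endothelial genes at -1.10 (-1.97 to -0.64). The 95% intervals in this and the next paragraph come from resampling the genes of a set 10000 times with the arrays fixed. They do not measure the spread between samples, and they treat genes that vary together as independent. After quantile normalization the median of the hepatocyte list was -4.53 (-4.88 to -3.94). The deposited arrays were already nearly alike, with medians between 5.52 and 5.63, so this step could hardly move a list at -4.42. It changed the genes called in carcinomas from 12544 to 11712, but it cannot decide on scaling between arrays. A change of expression within tumour cells, and a rise of stellate cells together with a loss of hepatocytes, stay open as hypotheses, and neither was tested.

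Of the 35 genes that phenobarbital raised in non-tumour liver, 18 were lower and 6 higher in adenomas on the same diet, with a median of -0.81 (95% interval -2.21 to 0.02) and medians per adenoma from -0.86 to -0.36. For the 18 lower genes (median -2.52, -2.74 to -1.81) control arrays that were high by chance are argued against: 15 to 17 genes chosen without 1 phenobarbital array lay below that array by medians of -2.74 to -2.40, with interval ends of -1.44 or lower. The hepatocyte list had a median of -0.24 (-0.42 to -0.10), with its interval above -0.45, the bound set for these 18 genes. That bound was taken from the fall for which the genes were picked, so the bound itself decides nothing. A lower share of hepatocytes alone would lower the hepatocyte list as far as these genes. Of the 27 genes of that list 2 were lower and 1 higher past the test, and its interval lay apart from that of the 18 genes. For the 18 genes these values argue against a lower share as the only cause, although picking them for falling may overstate their fall. Over all 35 genes a lower share stays open, since the interval of the hepatocyte list contains -0.20, the bound set for the whole set. Control arrays high by chance stay open there too: 8 genes chosen on phenobarbital arrays 1 and 2 differed in adenomas from arrays 3 to 5 by -2.68 (-4.38 to 1.07), too few genes to decide. A weaker response to the drug in adenoma cells is a hypothesis that was not tested.

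Untreated non-tumour arrays 3 and 4 stood apart, with Mki67 at 6.98 and 6.86 against 5.04 to 5.38 and Glul at 12.39 and 12.25 against 13.13 to 13.37 in the other 3. Carcinoma tissue in these samples is argued against: the 50 genes most raised in carcinomas gave shares of 0 and 0.0385%, where the cell cycle list gave 11.7 and 9.03%. Immune cells do not account for both arrays by these lists, since array 3 scored 0 for macrophage and 0 for T and NK cell genes against the middle of the 5 untreated arrays, within the range of the other 3 (-0.48 to 0.14 and -0.17 to 0). They stay open for array 4, which scored 0.31 and 0.17, above the other 3 on both lists. Differences between mice were not tested.

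In each remaining comparison 1 of 100 splits of the same arrays, the real 1, gave as many genes. This argues against chance only if the arrays are independent samples, which the labels do not state. Mice or batches shared within a group were not tested. Splits that mix groups also put the group difference into the spread, which lowers their counts. The real count for phenobarbital was 39 and the highest other 3, for carcinomas 12544 and 5478, for adenomas 4470 and 92, and between the tumour groups 11308 and 4781, where each highest other split kept 4 of 5 arrays together.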

How the results depend on the processing

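The alternative without untreated arrays 3 and 4 was chosen only after the results were seen, and all other alternatives were planned. The count for phenobarbital rose from 39 to 205 genes with array quality weights and to 265 with only the 2 groups fitted, all 39 among both, and the tumour arrays' larger spread no longer enters the second fit. The Apc difference in adenomas, 0.52, was 0.15 with the mean of all probe sets (adjusted p = 0.22), where 3 dimmer probe sets enter. With an estimated correlation the lists called fell to 3 for phenobarbital and to 0, 0, 0 and 0 for carcinomas, adenomas, the tumours compared and the difference of tumour effects. Fry called 3, 31, 15, 28 and 27 lists in the same order, and it asks whether the genes of a list move on balance 1 way, without reference to other genes. The stellate cell list in the phenobarbital comparison, without a call at a median of 0.04, turned to a call upward without untreated arrays 3 and 4 (0.17, adjusted p = 0.0027). The cause was not tested.

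Leaving out 1 array at a time gave 23 to 38 genes for phenobarbital, 11964 to 12302 for carcinomas, 3719 to 4526 for adenomas, 10767 to 11150 between tumours, 8031 to 8529 for the difference and 2525 to 2956 shared in direction between tumour effects (2972 with all arrays). The lists called ranged from 9 to 13, 21 to 23, 14 to 16, 22 to 24 and 19 to 21. Apc ranged from -0.35 to -0.26, 1.78 to 1.89, 0.47 to 0.59, -1.67 to -1.55 and -1.37 to -1.26.

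The groups share replicate numbers, but the labels do not say that these pair samples, and over 30 pairs same-numbered arrays deviated together with r from -0.11 to 0.13, 1 of them over 0.1, and 7 correlated best with their own number. With the replicate number as a block the counts were 39, 12415, 4312, 11180 and 8309. Over all settings except the estimated correlation and fry, calls changed under at least 1 setting for 54 results of single genes and 27 of lists. Counted once per result and setting, gene calls were weaker 285 times, stronger 12 and reversed 0. List calls were weaker 43 times, stronger 42 and reversed 1. Centring each array on its median moved the median fold of all genes in carcinomas from -0.118 to -0.182 and in the difference of tumour effects from 0.08 to 0.179. The filter on dim probe sets changed the sign of both medians, to 0.084 and -0.024. The check of RNA quality from control probe sets was not run, and folds of genes near the floor of the arrays are limited by background.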

Other observations

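Of the tests in this part, the fit without untreated arrays 3 and 4 was chosen only after the results were seen. Single arrays within the tumour groups differed widely in some named genes. Meg3 read 5.62, 13.25, 7.41, 10.62 and 6.85 in adenomas 1 to 5, and 11.30 in carcinoma 3. Cyp2b10 read 7.64, 13.22, 11.01, 12.46 and 9.24 in adenomas 1 to 5. Wif1 read 6.98, 3.26, 7.12, 3.60 and 3.23 in the same order, against 13.73 ± 0.03 (SD, n = 5) in carcinomas. Of the 4 measured genes of the imprinted Dlk1-Dio3 cluster, a list too short for a list test, 2 fell in carcinomas and 0 passed in adenomas or with phenobarbital. The spread used for the phenobarbital test includes the tumour arrays, among which Meg3 varied most. Both carcinoma calls were weak. Dlk1 (-0.23, adjusted p = 0.024) lost its call without untreated array 1 (-0.19, adjusted p = 0.073) or carcinoma array 5 (-0.18, adjusted p = 0.078), with quantile normalization (-0.14, adjusted p = 0.17) and without untreated arrays 3 and 4 (-0.24, adjusted p = 0.061). Mirg (-0.75, adjusted p = 0.019) lost it without untreated array 5 (-0.64, adjusted p = 0.053) and with the mean of all probe sets (-0.51, adjusted p = 0.26).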
